A study of Mus musculus with 12 samples.

How the data were processed

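The authors deposited 1 table of expression array intensities for 12 samples of mouse dorsal skin. According to the submitters' processing notes, these intensities come from RMA (background correction, normalization between arrays and 1 value per transcript cluster) in Affymetrix Expression Console. Versions of both are not given in the sources used here, and neither are the probe filters. The plan written before the files were opened assumed log2 values. The deposited intensities lie on a linear scale (2.5 to 18385, array medians 15.7 to 18.8), so log2 was taken here before any step.

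Each sample is a pool of skin from several mice, read on 1 array. The labels give 6 groups: WT, IL-6KO, IL-17C+ involved, IL-17C+ uninvolved, IL-17C+KO involved and IL-17C+KO uninvolved, where IL-17C+ stands for the transgene and KO for loss of IL-6. Every group has 1 pool at 10 weeks and 1 at 14 weeks, and these 2 ages are the replicates. The samples were grouped by their labels only and were not regrouped by any measured value. Whether the involved and uninvolved pools of a genotype come from the same mice is not given in the sources used here.

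The table has 41345 rows, of which 23521 name 1 gene, 1814 name several and 16010 name none. Only rows naming 1 gene were used for the gene tests. For the 1082 genes with more than 1 row, the row with the highest mean over all arrays stood for the gene, which left 22180 genes. Of these, 21994 identifiers were found in the RefSeq gene table supplied for GRCm38.p6, all with the same symbol. That table served for names and for the order of neighbouring genes. The rows naming several genes or none were tested apart with the same model, as 17824 rows.

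Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend). The model holds group plus age over all 12 arrays, with age as a block, 5 residual degrees of freedom and 7.65 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 22180 genes of a comparison, and a gene passed at an adjusted p under 0.05. Standard errors are the moderated ones of limma. There were 13 comparisons: 9 between groups, the transgene by IL-6 interaction in involved skin, the site by IL-6 interaction in transgenic skin, 14 against 10 weeks, and the age by IL-6 interaction in transgenic skin. The last used a separate fit with 1 age slope per genotype and 2 residual degrees of freedom. Ages were also exchanged within groups, 32 ways for age and 8 ways for its interaction.

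The 24 gene lists were fixed before the data were examined. They are the IL-17 family, IL-6 family ligands and receptors, STAT3-responsive genes, the IL-1 and IL-36 family, TNF with IL-20 family and other cytokines, chemokines, antimicrobial proteins and alarmins, and stress keratins with the inducible cornified envelope. Further lists cover homeostatic epidermal differentiation, proliferation, EGF family ligands and receptors, interferon-stimulated genes, tissue remodelling proteases, and markers of neutrophils, T cells, macrophages and dendritic cells, and mast cells. The list of tissue remodelling proteases, called proteases below, also holds the inhibitors Timp1 and Timp3, the matrix gene Tnc and the receptor Plaur. Timp1 is in the list of STAT3-responsive genes as well. The tissue lists are hair shaft and follicle, melanocyte, sebaceous gland, adipocyte, skeletal muscle, fibroblast and collagen, and endothelial genes. A list of Y-linked genes gave values per array only. Lists were tested with limma camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 24 lists of a comparison. Members were also counted past the threshold over all genes and adjusted over the list alone. List members without a row of their own were not analysed here.

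Il6 and Il17c are named in every comparison. Other named genes follow a rule set beforehand: the 10 largest positive and 10 largest negative differences that passed with the same direction at both ages, without predicted loci, small RNAs, olfactory and vomeronasal receptors, and immunoglobulin or T cell receptor segments. From a list, up to 3 members that passed and the largest that did not pass were eligible, or the 2 largest where none passed. Where fewer than 5 genes passed, the 5 with the smallest p were eligible. For the effect of IL-6 loss at each age, where 1 array stands on each side, differences were given without a test. List medians at 1 age were placed among those of 10000 random lists of the same size matched on expression.

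The following alternatives were planned before the data were examined: no replicate block, a replicate block of genotype and age for involved against uninvolved skin, eBayes without the trend, only genes above the array median in at least 2 arrays, another quantile normalization, and a 1.5-fold minimum. Also planned were the mean of all rows of a gene, the Y-linked mean or the skeletal muscle list mean as a covariate, WT as the control, other age slopes, leaving out each array in turn, and Spearman for the correlation. Added after the data were seen were a fit on only the 4 arrays of IL-17C+ involved and WT, and a fit without the 10-week WT and IL-6KO arrays.

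The scripts were tested on simulated data of the same layout. A log2 change of 1 was recovered in 24 of 50 genes, and changes of 2, 3 and 4 in 50 of 50 each. There were 17 false calls among 22180 genes in each of 2 simulated comparisons and 14 in another. As a share of all calls in these comparisons, the false calls exceeded what the adjusted p threshold allows on average. Comparisons without a simulated change gave 0 calls in IL-6KO against WT, 0 for age and 1 for the age by IL-6 interaction. A chemokine list raised by 1 was called, and 0 of 23 unchanged lists were. Genes were simulated independently of each other, so list calls under correlation between genes were not tried. In the data 156 of 168 list calls were weaker with an estimated correlation.

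Raw array files were not used here. Skin histology, clinical scores and single mice are not analysed here.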

Results

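RNA of dorsal skin from C57Bl/6 mice was measured on 12 expression arrays. The series asks whether psoriasis-like inflammation driven by a transgene for the cytokine IL-17C lasts when IL-6 is missing. Its samples are labelled WT, IL-6KO, IL-17C+ (transgenic) involved and uninvolved, and IL-17C+KO (transgenic and without IL-6) involved and uninvolved. Each of these 6 groups has n = 2 pools, 1 at 10 weeks and 1 at 14 weeks. The pools are described as skin of male and female mice, of 4 mice each for WT and IL-6KO at 10 weeks and 5 each otherwise. Involved and uninvolved pools may share mice, which is not given in the sources used here, and 2 arrays per group limit the precision of every value. Differences are log2 values with the standard error of limma, and adjusted p-values are those of limma with Benjamini-Hochberg over 22180 genes. These p-values measure only the spread between these 12 pools, which is not the spread between mice and includes that of sample preparation. No group has 2 pools of 1 age, so this spread also holds any group effect that changes with age.

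Il17c, the transgene, did not follow the labels. At 10 and 14 weeks its log2 level was 4.67 and 4.96 in skin labelled WT, 5.81 and 6.63 in IL-17C+ involved, but 4.74 and 4.16 in IL-17C+ uninvolved skin. In skin labelled IL-6KO, which should carry no transgene, it read 6.30 and 6.17, against 5.32 and 5.62 in IL-17C+KO involved and 6.16 and 6.25 in IL-17C+KO uninvolved skin. Il6, the disrupted gene, read 2.92 and 2.88 in WT, 2.68 and 2.79 in IL-6KO, 4.23 and 3.21 in IL-17C+ involved, and 3.28 and 3.02 in IL-17C+ uninvolved skin. In skin labelled IL-17C+KO it read 3.14 and 4.64 in involved and 4.93 and 5.00 in uninvolved skin, the last 3 being the highest of all arrays. Il6 lay below the array medians in WT (4.23 and 3.97) and in IL-6KO skin (4.19 and 3.99), so a loss between them could hardly show. Whether the Il17c row reads the transgene, and whether the Il6 row lies in the disrupted part of the gene, is not given in the sources used here, so the Il6 row checks no label by itself. All group names are therefore labels, and every direction drawn from them rests on these labels. Il17c goes against them if its row reads the transgene.

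**Figure D1:**
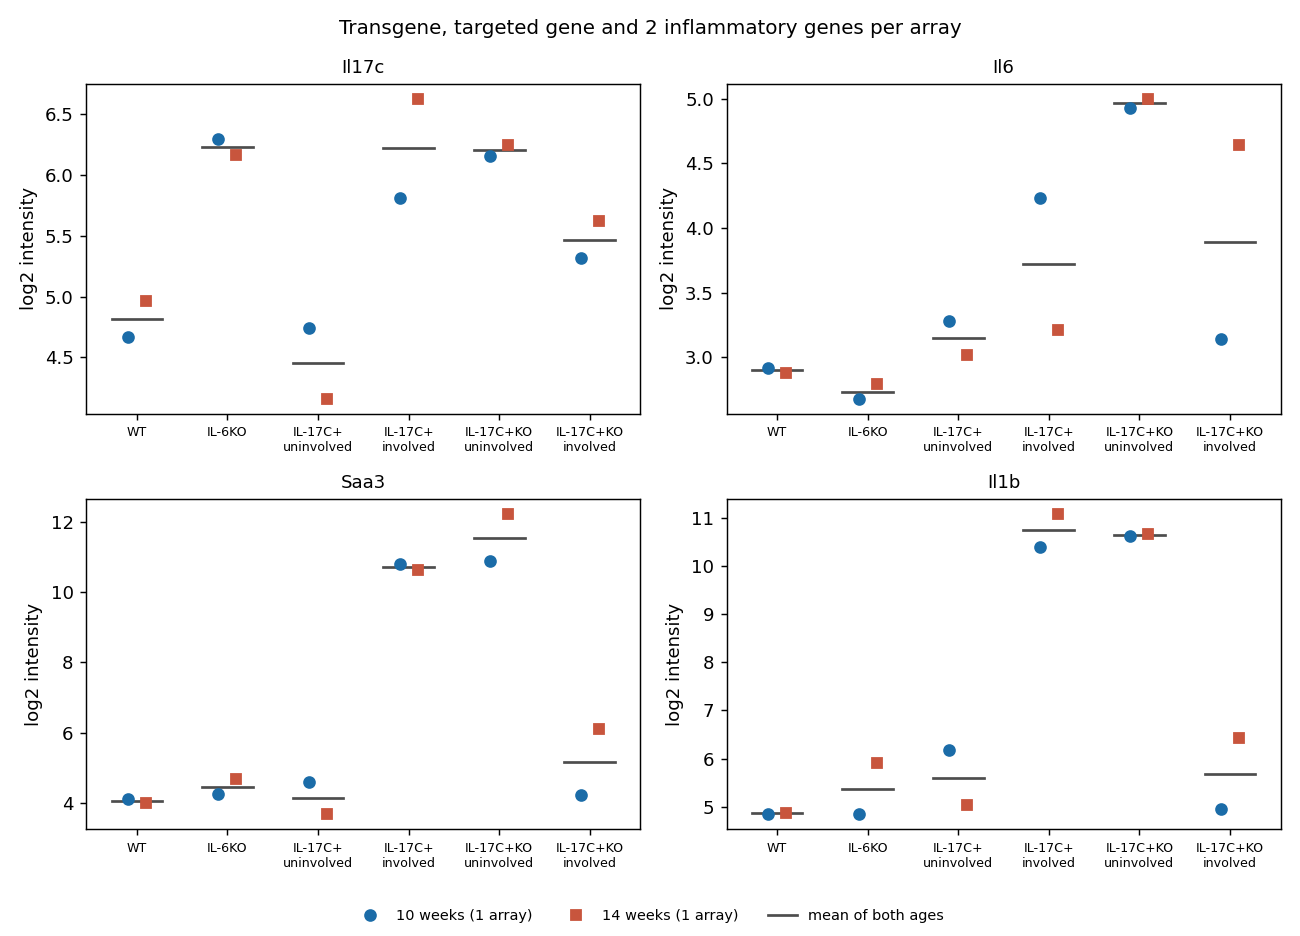
Log2 level (vertical axis) of Il17c, Il6, Saa3 and Il1b on each array, by labelled group, with 10 weeks as blue circles, 14 weeks as red squares and the group mean as a line. Saa3 averaged 4.06 in WT, 10.71 in IL-17C+ involved, 5.16 in IL-17C+KO involved and 11.54 in IL-17C+KO uninvolved skin.

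The pools also differed in tissue and sex make-up. The mean of the skeletal muscle list (contractile genes of the muscle under the dermis) was 10.06 in WT, 10.12 in IL-17C+ uninvolved and 9.49 in IL-17C+KO involved skin, but 7.71 in IL-17C+ involved, 8.56 in IL-17C+KO uninvolved and 8.71 in IL-6KO skin. Muscle genes thus moved with the groups, opposite to antimicrobial genes, whose means in the same order were 4.36, 4.40, 5.34, 6.97, 7.23 and 5.55. Xist, expressed from the inactive X chromosome of females, ranged from 5.55 in IL-6KO to 9.76 in IL-17C+ uninvolved skin, both at 14 weeks, on 11 arrays. In WT at 10 weeks it read 4.15, below the median of that array (4.23), which taken alone goes against females in this pool. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty ranged from 5.15 in WT to 6.67 in IL-6KO skin, both at 14 weeks. In WT at 10 weeks it was 5.34, no higher than the 5.35 of the IL-17C+ uninvolved pool with the highest Xist. The sex make-up of that WT pool therefore stays open.

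**Figure D2:**
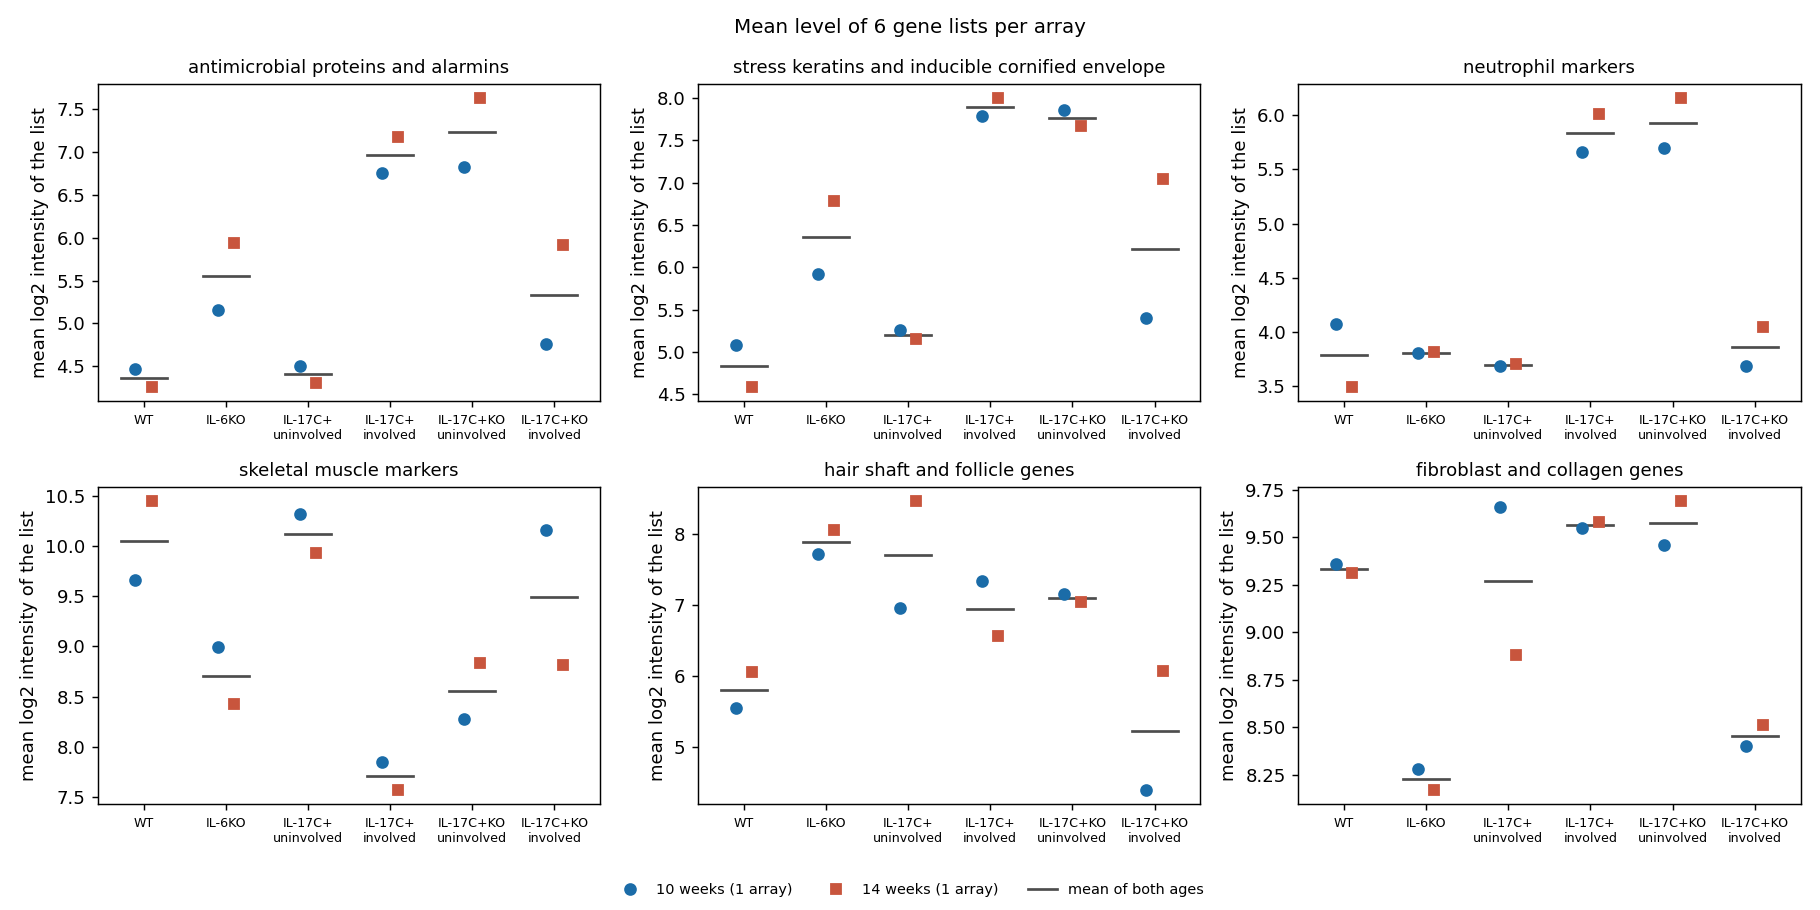
Mean log2 level (vertical axis) of 6 gene lists on each array, by labelled group, with 10 weeks as blue circles, 14 weeks as red squares and the group mean as a line. Skeletal muscle markers are lowest (7.71) and antimicrobial genes high (6.97) in IL-17C+ involved skin.

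What does the transgene do in affected skin with IL-6 present? In skin labelled IL-17C+ involved, Stfa3 rose by 8.24 ± 1.08 over WT (303-fold, adjusted p = 0.00219), Saa3 by 6.64 ± 0.51 (adjusted p = 7.87e-05) and Il1b by 5.88 ± 0.46 (adjusted p = 7.87e-05), each at both ages. Stfa3 lay below the array medians in WT (4.23 and 3.97), so the size of its rise is uncertain. Krt6b (6.50 ± 0.66), Krt16 (5.70 ± 0.73), S100a8 (6.39 ± 0.72) and S100a9 (6.14 ± 0.75), keratins and alarmins of stressed epidermis, rose as well. Retnla, a product of alternatively activated macrophages, fell by 5.10 ± 0.72, the suprabasal keratin Krt77 by 4.22 ± 0.54, Krt15 of follicle stem cells by 3.13 ± 0.43 and the itch receptor Il31ra by 2.95 ± 0.37. Il17c rose by 1.40 ± 0.30 (adjusted p = 0.0328), and Il6 differed by 0.82 ± 0.41 without passing (adjusted p = 0.467). Of 22180 genes 399 passed, 244 higher and 155 lower, all with 1 direction at both ages. A gene whose direction differs between the ages can hardly pass, because that disagreement widens its standard error. One direction at both ages among called genes, here and in the comparisons below, therefore follows from the call and is no replication.

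By list, 15 of 22 stress keratin and inducible envelope genes rose, and 20 when adjusted over the list alone (median 2.66, camera adjusted p = 3.12e-28). Antimicrobial genes (8 of 16, 11 adjusted over the list alone, median 1.73), neutrophil markers (7 of 14, 11 adjusted over the list alone, median 1.52) and the IL-1 and IL-36 family (7 of 14, 11 adjusted over the list alone, median 1.38) rose too, led by Saa3, Retnlg (5.08 ± 0.46) and Il1b. So did the protease list (8 of 16 higher and 1 lower, 10 and 1 adjusted over the list alone, median 1.66), mast cell markers (4 of 9, 7 adjusted over the list alone, median 1.45) and STAT3-responsive genes (1 of 15, Timp1 at 3.10 ± 0.41, and 7 adjusted over the list alone, median 0.61). Not all members of the protease list are proteases, and Timp1 counts in it too, so these lists are not independent. Skeletal muscle markers fell, with 19 of 21 lower, 20 adjusted over the list alone and a median of -2.32. These 8 lists passed camera at adjusted p of 1.01e-06 or less, and each had adjusted p = 0.079 with an estimated correlation, which ends the call. The test fry asks whether the genes of a list move 1 way on balance, and its adjusted p lay between 0.0112 and 0.0217 for the 8.

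Chemokines (6 of 24 higher, also 6 adjusted over the list alone, median 0.39, adjusted p = 0.000161, and adjusted p = 0.194 with an estimated correlation) were led by Cxcl3 at 4.54 ± 0.43, Ccl3 at 4.15 ± 0.61 and Cxcl5 at 3.82 ± 0.32. Proliferation genes such as Birc5 (1.48 ± 0.26) passed in 3 of 26, and 12 adjusted over the list alone (median 0.76, adjusted p = 2.24e-13, and adjusted p = 0.199 with an estimated correlation). Hair genes (2 of 30, 11 adjusted over the list alone, median 1.25, adjusted p = 1.02e-09 and adjusted p = 0.357 with an estimated correlation) and melanocyte markers (3 of 10, 4 adjusted over the list alone, median 0.51, adjusted p = 0.000207 and adjusted p = 0.161 with an estimated correlation) were higher. Endothelial markers (1 of 15, Selp at 1.93 ± 0.36, 2 adjusted over the list alone, median 0.37, adjusted p = 0.00942) and interferon-stimulated genes (0 of 18, 2 lower adjusted over the list alone, median -0.29, adjusted p = 0.00406) both had adjusted p = 0.428 with an estimated correlation. Homeostatic differentiation genes split, with Casp14 at 3.17 ± 0.59 and Krt77 lower (2 higher and 3 lower of 27, 10 and 4 adjusted over the list alone, median 0.27, adjusted p = 0.0209, and adjusted p = 0.549 with an estimated correlation). Macrophage and dendritic cell markers split too, Cd14 at 3.42 ± 0.45 and H2-Ab1 at -1.87 ± 0.33 (2 higher and 3 lower of 20, 3 and 5 adjusted over the list alone, median -0.23, adjusted p = 0.025, and adjusted p = 0.5 with an estimated correlation).

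The other 8 lists did not pass camera. T cell markers had 0 of 16 members past either threshold (median -0.03, adjusted p = 0.393), the largest difference being Cd3g at -1.38 ± 0.52. The IL-17 family had only Il17c past both thresholds of its 11 genes (median -0.04 but mean 0.09 and test upward, adjusted p = 0.783). In the IL-6 family Il31ra fell and Osm, at 1.29 ± 0.31, did not pass over all genes (1 lower of 14, 1 higher and 3 lower adjusted over the list alone, median -0.11, adjusted p = 0.24). Among TNF, IL-20 family and other cytokines, Il20ra fell by 2.23 ± 0.24 while Il19 rose by 1.18 ± 0.23 (2 higher and 1 lower of 20, 5 and 2 adjusted over the list alone, median 0.10, adjusted p = 0.325). EGF family genes had Hbegf at 1.89 ± 0.39 and Btc at -1.09 ± 0.23 (1 higher and 1 lower of 12, 5 and 1 adjusted over the list alone, median 0.07, adjusted p = 0.0819). Sebaceous genes had Scd3 at -2.61 ± 0.43 and Elovl3 at 2.42 ± 0.50 (1 and 1 of 12, 3 and 3 adjusted over the list alone, median 0.20, adjusted p = 0.798). Adipocyte markers had Car3 at -1.82 ± 0.33 (1 lower of 13, also 1 adjusted over the list alone, median -0.12, adjusted p = 0.24). Fibroblast and collagen genes had none past the threshold over all genes, with Postn at 1.13 ± 0.36 (0 of 16, 2 higher and 1 lower adjusted over the list alone, median 0.38, adjusted p = 0.181).

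The count of 399 genes in this comparison fell to 65 (57 higher, 8 lower) without the 10-week and 119 (94 higher, 25 lower) without the 14-week IL-17C+ involved array, and to 149 (74 higher, 75 lower) without the 14-week WT array. Most calls were lower without the 10-week WT array (157 higher, 312 lower) and without the 10-week WT and IL-6KO arrays (182 higher, 407 lower), while a fit on only the 4 arrays of these groups called 883 (463 higher, 420 lower). With the skeletal muscle list mean as a covariate limma called 0 genes (1002 at unadjusted p under 0.05): Stfa3 went from 8.24 ± 1.08 to 3.38 ± 1.73, S100a8 from 6.39 ± 0.72 to 2.72 ± 1.04, Krt6b from 6.50 to 3.30 ± 0.99 and Krt16 from 5.70 to 1.70 ± 0.94. Saa3, which shrank less, went from 6.64 ± 0.51 to 5.70 ± 1.07, Casq1 of muscle from -3.48 to -0.92 ± 0.74 and Mybpc2 from -2.87 to 0.68 ± 0.66. Casq1 is a member of the list that makes up the covariate, so its shrinkage was built in. The calls ended because the covariate follows the groups, so that the median standard error of all genes was 2.21 times as large and many differences shrank. Il6 then turned to -0.43, and the medians of the homeostatic differentiation, proliferation and hair lists to -0.13, -0.13 and -0.03.

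How far does affected transgenic skin differ from uninvolved skin of the same genotype? Between skin labelled IL-17C+ involved and IL-17C+ uninvolved, Stfa3 rose by 7.84 ± 1.08, Saa3 by 6.56 ± 0.51, S100a9 by 6.31 ± 0.75, Krt6b by 5.82 ± 0.66, Retnlg of neutrophils by 5.45 ± 0.46 and Il1b by 5.14 ± 0.46. On the 14-week IL-17C+ uninvolved array Stfa3 lay below the array median (4.06), so the size of its rise is uncertain. Retnla fell by 5.02 ± 0.72, Krt77 by 3.99 ± 0.54, the epidermal gene Skint6 by 3.61 ± 0.33 and Il31ra by 3.57 ± 0.37. Il17c rose by 1.77 ± 0.30 (adjusted p = 0.00989), and Il6 differed by 0.57 ± 0.41 (adjusted p = 0.648). The Il17c direction rests on the IL-17C+ uninvolved label, which Il17c contradicts if its row reads the transgene. limma called 357 genes, 172 higher and 185 lower, all with 1 direction at both ages. Stress keratins rose (13 of 22, 18 adjusted over the list alone, median 2.17, adjusted p = 3.58e-23, and adjusted p = 0.0968 with an estimated correlation). Neutrophil markers rose as well (7 of 14, 12 adjusted over the list alone, median 1.64, adjusted p = 6.54e-19, and adjusted p = 0.0697 with an estimated correlation). Muscle markers fell (18 of 21, 20 adjusted over the list alone, median -2.42, adjusted p = 5.34e-31, and adjusted p = 0.0996 with an estimated correlation), and 15 of 24 lists passed in all, 0 of them with an estimated correlation. The 357 genes became 82 (61 higher, 21 lower) and 63 (42 higher, 21 lower) without the 10- or 14-week IL-17C+ involved array (Il6 at -0.08 without the former). They became 170 (136 higher, 34 lower) and 224 (67 higher, 157 lower) without the 10- or 14-week IL-17C+ uninvolved array (fibroblast median 0.00 and test downward without the latter), and 666 (239 higher, 427 lower) without the 10-week WT and IL-6KO arrays. With the skeletal muscle list mean as a covariate limma called 0 (720 at unadjusted p under 0.05, median standard error 2.26 times as large). Stfa3 went from 7.84 ± 1.08 to 2.84 ± 1.77, S100a9 from 6.31 to 3.34 ± 1.37, Krt6b from 5.82 to 2.53 ± 1.01 and Sprr2d from 5.67 to 0.83 ± 1.10, while Saa3 shrank less, from 6.56 ± 0.51 to 5.59 ± 1.09. Il6 turned to -0.72, Mybpc2 from -3.00 to 0.65 and the proliferation median from 0.54 to -0.26.

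Does skin of transgenic mice without visible disease differ from WT? Hair shaft genes rose in skin labelled IL-17C+ uninvolved, the keratin-associated genes Krtap19-1 by 5.41 ± 0.73, Krtap6-5 by 5.28 ± 0.71 and Krtap3-1 by 3.22 ± 0.43 and the keratin Krt33a by 2.64 ± 0.37, each at both ages. Il17c differed by -0.37 ± 0.30 (adjusted p = 0.904), against the label if its row reads the transgene, and Il6 by 0.25 ± 0.41 (adjusted p = 0.947). Saa3 averaged 4.14 here and 4.06 in WT. limma called 12 genes, all higher (1261 at unadjusted p under 0.05, 1109 by chance). Only the hair list passed camera (2 of 30, 23 higher and 1 lower adjusted over the list alone, median 1.95, adjusted p = 1.73e-31, and adjusted p = 0.739 with an estimated correlation). Antimicrobial genes had 0 of 16 past either threshold (median -0.08 but mean 0.04 and test upward, adjusted p = 0.869). The count was 0 without the 10-week WT array (804 at unadjusted p under 0.05), 87 (13 higher, 74 lower) without the 14-week WT array, 39 and 2 without the 10- or 14-week IL-17C+ uninvolved array (Il17c at 0.06 without the latter), and 30, 30, 32 and 32 without an array of IL-17C+ involved or IL-17C+KO involved skin at 10 or 14 weeks. It was 7 with no replicate block, 3 with eBayes without the trend, 3 with quantile normalization again, 19 with only genes above the array median in at least 2 arrays, 27 with the Y-linked mean as a covariate and 1, a lower one, without the 10-week WT and IL-6KO arrays.

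What differs between the 2 groups labelled as free of the transgene? Skin labelled IL-6KO had higher hair shaft genes than WT, Krtap19-1 by 6.10 ± 0.73 (adjusted p = 0.00578) and Krtap3-1 by 3.49 ± 0.43, and higher epidermal stress genes, Stfa3 by 6.09 ± 1.08 (adjusted p = 0.0341), Stfa1 by 4.61 ± 0.71 and Lcn2 by 2.47 ± 0.45. The WT means of Krtap19-1 and Stfa3 lay below the WT array medians (4.23 and 3.97), so the size of their rise is uncertain. The proton pump gene Atp12a rose by 4.65 ± 0.41 (adjusted p = 0.00125). Collagen genes fell, Col1a2 by 2.29 ± 0.30, Col1a1 by 2.21 ± 0.30 and Col3a1 by 2.16 ± 0.32, as did Krt15 by 2.35 ± 0.43. Il17c differed by 1.42 ± 0.30 without passing (adjusted p = 0.0661) although the label gives no transgene, and Il6 by -0.16 ± 0.41 (adjusted p = 0.965). limma called 101 genes, 80 higher and 21 lower, at both ages. Hair genes (9 of 30, 26 adjusted over the list alone, median 2.22, adjusted p = 1.07e-30) and antimicrobial genes (2 of 16, 8 adjusted over the list alone, median 1.06, adjusted p = 1.03e-09) rose. Fibroblast genes (4 of 16, 10 adjusted over the list alone, median -0.91, adjusted p = 7.99e-18) and muscle markers (2 of 21, 13 adjusted over the list alone, median -1.17, adjusted p = 3.58e-16) fell. All 4 lists had adjusted p = 0.211 with an estimated correlation. STAT3-responsive genes had 0 of 15 past the threshold, 1 lower adjusted over the list alone, and a median of 0.04 where mean (-0.12) and test were downward (adjusted p = 0.401). The count was 13 (7 higher, 6 lower) and 37 (14 higher, 23 lower) without the 10- or 14-week WT array, so the balance turned in the latter. It was 24 and 7 (7 higher, 0 lower) without the 10- or 14-week IL-6KO array, 153 and 152 without the 10- or 14-week IL-17C+KO involved array, and 13 without the 10-week WT and IL-6KO arrays. It was 26 with no replicate block, 63 with eBayes without the trend, 143 (90 higher, 53 lower) with quantile normalization again, and 66 with the Y-linked mean as a covariate (43 higher, 23 lower).

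Does the inflammation of affected skin last without IL-6? In skin labelled IL-17C+KO involved, inflammatory genes were far below IL-17C+ involved skin: Saa3 fell by 5.54 ± 0.51 (adjusted p = 0.000392), Il1b by 5.06 ± 0.46 (adjusted p = 0.000392), the matrix gene Tnc by 4.65 ± 0.55, the neutrophil attractant Cxcl3 by 4.59 ± 0.43, Retnlg by 4.54 ± 0.46 and Acod1 of activated myeloid cells by 4.14 ± 0.31. Krt77 rose by 3.93 ± 0.54, Il22ra2, a decoy receptor for IL-22, by 3.21 ± 0.33, the envelope gene Lce1m by 3.08 ± 0.47 and Myh1 of muscle by 2.97 ± 0.46. Saa3 averaged 5.16 here, 4.47 in IL-6KO and 4.06 in WT skin. Il17c differed by -0.75 ± 0.30 (adjusted p = 0.421) and Il6 by 0.17 ± 0.41 (adjusted p = 0.958), neither passing. limma called 144 genes, 51 higher and 93 lower, at both ages. An exchange of the labels IL-17C+KO involved and uninvolved, left open below, would leave no fall in the antimicrobial and neutrophil lists. Their means were 7.23 and 5.93 in IL-17C+KO uninvolved and 6.97 and 5.83 in IL-17C+ involved skin.

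Among the lists of this comparison, neutrophil markers (7 of 14, 9 adjusted over the list alone, median -1.76, adjusted p = 7.65e-20), proteases (6 of 16, 12 lower and 1 higher adjusted over the list alone, median -2.27, adjusted p = 2.12e-19) and mast cell markers (3 of 9, 7 adjusted over the list alone, median -1.27, adjusted p = 4.29e-13) fell. Each had adjusted p = 0.067 with an estimated correlation. Stress keratins such as Krt6a (-2.79 ± 0.45) fell (3 of 22, 16 adjusted over the list alone, median -1.23, adjusted p = 5.42e-17), while muscle markers rose (5 of 21, 19 adjusted over the list alone, median 1.69, adjusted p = 3.91e-25), both with adjusted p = 0.112 with an estimated correlation. Antimicrobial genes fell (2 of 16, 10 adjusted over the list alone, median -1.30, adjusted p = 1.62e-11, and adjusted p = 0.0951 with an estimated correlation). Fibroblast genes fell too, led by Postn at -2.28 ± 0.36 (4 of 16, 14 adjusted over the list alone, median -0.99, adjusted p = 8.07e-19, and adjusted p = 0.107 with an estimated correlation). STAT3-responsive genes fell as a list (1 of 15, Timp1 at -2.79 ± 0.41, 5 adjusted over the list alone, median -0.24, adjusted p = 0.00013, and adjusted p = 0.145 with an estimated correlation). Of the IL-6 family Osm fell by 1.73 ± 0.31 and Il31ra rose by 2.33 ± 0.37, and T cell markers had 0 of 16 past either threshold. In all 15 of 24 lists passed, 3 upward and 12 downward, and 0 did with an estimated correlation. The 144 genes became 38 (3 higher, 35 lower) and 53 (5 higher, 48 lower) without the 10- or 14-week IL-17C+ involved array, 23 (2 higher, 21 lower) and 244 (111 higher, 133 lower) without the 10- or 14-week IL-17C+KO involved array (Il6 at -0.70 without the latter and -0.48 without the 14-week IL-17C+ involved array, proliferation median 0.02 without the former). They became 225 and 218 without the 10- or 14-week IL-17C+ uninvolved array, and 225 (114 higher, 111 lower) without the 10-week WT and IL-6KO arrays. With the Y-linked mean as a covariate 125 passed (19 higher, 106 lower). With the skeletal muscle list mean as a covariate limma called 0 (846 at unadjusted p under 0.05, median standard error 1.81 times as large). Tnc went from -4.65 ± 0.55 to -2.98 ± 0.79 and Retnlg from -4.54 ± 0.46 to -2.92 ± 0.61, Saa3 from -5.54 ± 0.51 to -4.83 ± 0.87, and the medians of the stress keratin and proliferation lists turned to 0.05 and 0.35.

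And in uninvolved skin? There the loss of IL-6 went with the reverse. Skin labelled IL-17C+KO uninvolved exceeded IL-17C+ uninvolved skin by 7.57 ± 1.08 in Stfa3, 7.40 ± 0.51 in Saa3 (adjusted p = 6.55e-05), 6.16 ± 0.75 in S100a9, 6.01 ± 0.46 in Retnlg and 5.04 ± 0.46 in Il1b. The size of the Stfa3 difference is uncertain, because Stfa3 lay below the array median (4.06) on the 14-week IL-17C+ uninvolved array. Retnla fell by 3.73 ± 0.72, Il31ra by 3.09 ± 0.37, Scd3 of sebaceous glands by 2.99 ± 0.43 and Krt77 by 2.82 ± 0.54. Il17c rose by 1.76 ± 0.30 (adjusted p = 0.0152), again a direction resting on the IL-17C+ uninvolved label, and Il6 differed by 1.81 ± 0.41 without passing (adjusted p = 0.0773). limma called 158 genes, 120 higher and 38 lower, at both ages. Antimicrobial genes (8 of 16, 14 adjusted over the list alone, median 1.94, adjusted p = 8.95e-27), neutrophil markers (7 of 14, 11 adjusted over the list alone, median 2.06, adjusted p = 8.65e-24) and proteases (8 of 16 higher and 1 lower, 12 and 1 adjusted over the list alone, median 1.55, adjusted p = 1.93e-19) rose, and stayed called at adjusted p = 0.0328 with an estimated correlation. Muscle markers fell (2 of 21, 19 adjusted over the list alone, median -1.49, adjusted p = 3.63e-24, and adjusted p = 0.106 with an estimated correlation). Leaving out the 10- or 14-week IL-17C+KO uninvolved array gave 78 and 59 genes (51 higher, 8 lower in the latter), and leaving out the 14-week IL-17C+ uninvolved array 64 (40 higher, 24 lower), with the fibroblast median at -0.03 and the hair median at -0.02 (its test turning upward) in the last case and the homeostatic differentiation median at -0.03 without the 10-week IL-17C+KO uninvolved array.

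What does the transgene do in affected skin when the control also lacks IL-6? Against skin labelled IL-6KO, IL-17C+KO involved skin had lower hair shaft genes, Krtap8-1 by -5.45 ± 0.88 (adjusted p = 0.0314), Krtap19-1 by -4.89 ± 0.73, Krtap16-3 by -4.86 ± 0.59 (adjusted p = 0.00868) and Krtap3-1 by -3.73 ± 0.43. On the 10-week IL-17C+KO involved array Krtap16-3 lay below the array median (4.04), so the size of its fall is uncertain. No inflammatory gene named above passed, with Retnlg at 0.44 ± 0.46, Stfa3 at -1.53 ± 1.08 and S100a7a at -1.71 ± 0.36 (adjusted p = 0.125). Il17c differed by -0.77 ± 0.30, below a control labelled as free of the transgene, and Il6 by 1.15 ± 0.41 (both adjusted p = 0.999). limma called 38 genes, all lower at both ages (875 at unadjusted p under 0.05, 1109 by chance). The hair list fell (8 of 30, 26 adjusted over the list alone, median -2.80, adjusted p = 1e-61, and adjusted p = 0.205 with an estimated correlation). Muscle markers were higher (0 of 21 past either threshold, median 0.72, adjusted p = 1.92e-08, and adjusted p = 0.672 with an estimated correlation). Stress keratins had a median of 0.02 with mean (-0.14) and test downward (0 of 22, adjusted p = 0.297). The count was 0 without the 10-week IL-17C+KO involved array (493 at unadjusted p under 0.05, muscle median -0.01), 2 and 0 without the 10- or 14-week IL-6KO array (1562 for the latter). It was 62 without any 1 of the 4 arrays of IL-17C+ involved or IL-17C+ uninvolved skin, and 2 without the 10-week WT and IL-6KO arrays. It was 14 with no replicate block, 15 with eBayes without the trend, 22 with quantile normalization again, and 0 with the skeletal muscle list mean as a covariate (553 at unadjusted p under 0.05). In that fit Krtap8-1 went from -5.45 ± 0.88 to -4.52 ± 0.92 and the median standard error was 1.22 times as large. With WT as the control 5 genes passed (4 higher, 1 lower), Krtap19-1 turned to 1.21, Krtap19-9b to 0.56, Krtap19-5 to 0.46, Krtap6-5 to 0.92 and Il17c to 0.65, and the medians of the muscle, fibroblast, macrophage and melanocyte lists to -0.53, -0.84, -0.32 and 0.15.

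The same question in uninvolved skin had a different outcome. In skin labelled IL-17C+KO uninvolved, Saa3 rose over IL-6KO by 7.08 ± 0.51 (135-fold, adjusted p = 0.000112), Retnlg by 5.54 ± 0.46, Il1b by 5.27 ± 0.46, Tnc by 5.13 ± 0.55, Cxcl3 by 4.60 ± 0.43 and Cxcl5 by 3.89 ± 0.32. Il6 rose by 2.23 ± 0.41 (adjusted p = 0.0388) between 2 groups that are both labelled as lacking it, and Il17c differed by -0.03 ± 0.30 (adjusted p = 0.992). In IL-6KO skin Il6 lay below the array medians (4.19 and 3.99), so the size of its rise is uncertain. Osm rose by 1.63 ± 0.31 and Il4ra by 1.57 ± 0.25, and the chloride channel regulator Clca3a2 fell 2.82-fold (adjusted p = 0.0488). limma called 88 genes, 87 higher and 1 lower, at both ages. Neutrophil markers (8 of 14, 11 adjusted over the list alone, median 1.84, adjusted p = 4.95e-21), proteases (6 of 16, 10 adjusted over the list alone, median 1.37, adjusted p = 2.33e-16) and STAT3-responsive genes (2 of 15, 9 adjusted over the list alone, median 0.82, adjusted p = 4.84e-13) rose and stayed called at adjusted p = 0.0474 with an estimated correlation. Fibroblast genes rose as well (4 of 16, 15 adjusted over the list alone, median 1.34, adjusted p = 3.32e-26, and adjusted p = 0.0657 with an estimated correlation). The count was 31 and 26 without the 10- or 14-week IL-6KO array (Il17c at 0.12 without the former), 55 and 15 without the 10- or 14-week IL-17C+KO uninvolved array, 164 and 162 without the 10- or 14-week IL-17C+ uninvolved array, and 34 (31 higher, 3 lower) without the 10-week WT and IL-6KO arrays, where Il17c was at 0.11. With WT as the control 308 genes passed (248 higher, 60 lower), Il17c passed at 1.39 (adjusted p = 0.0406), and the medians of the homeostatic differentiation, hair and macrophage lists turned to 0.44, 1.34 and -0.14.

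Which site of transgenic skin without IL-6 is the inflamed one? By their labels it is the uninvolved one. Saa3 was lower in skin labelled IL-17C+KO involved than in IL-17C+KO uninvolved skin by -6.38 ± 0.51 (adjusted p = 0.000175), Retnlg by -5.10 ± 0.46, Tnc by -5.04 ± 0.55, Il1b by -4.96 ± 0.46 and Cxcl5 by -3.87 ± 0.32. Krt77 rose by 2.75 ± 0.54, Il22ra2 by 2.43 ± 0.33, Il31ra by 1.85 ± 0.37 and Il20ra by 1.46 ± 0.24. Il17c differed by -0.74 ± 0.30 (adjusted p = 0.676) and Il6 by -1.08 ± 0.41 (adjusted p = 0.612). limma called 112 genes, 6 higher and 106 lower, at both ages. Antimicrobial genes (2 of 16, 12 adjusted over the list alone, median -1.58, adjusted p = 1.43e-20), proteases (7 of 16, 14 adjusted over the list alone, median -1.98, adjusted p = 1.42e-25) and neutrophil markers (8 of 14, 10 adjusted over the list alone, median -1.99, adjusted p = 3.38e-24) fell and stayed called at adjusted p = 0.0352 with an estimated correlation. Muscle markers were higher (0 of 21 past either threshold, median 0.93, adjusted p = 4.56e-13, and adjusted p = 0.21 with an estimated correlation), but only at 10 weeks: their mean level was 10.16 in involved and 8.28 in uninvolved skin at 10 weeks, and 8.82 and 8.84 at 14 weeks. The median of the homeostatic differentiation list was 0.02, its test downward, without the 14-week IL-17C+KO involved array. The count was 23 without the 10-week IL-17C+KO involved array, 47 and 16 without the 10- or 14-week IL-17C+KO uninvolved array, and 62 (7 higher, 55 lower) with a replicate block of genotype and age. With the skeletal muscle list mean as a covariate limma called 29 (2 higher, 27 lower), where Saa3 went from -6.38 ± 0.51 to -6.01 ± 0.62, Retnlg from -5.10 to -4.25 ± 0.44, Tnc from -5.04 to -4.16 ± 0.57 and the median standard error was 1.29 times as large.

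Does the effect of the transgene in affected skin depend on IL-6? Its difference between IL-6-deficient and IL-6-competent involved skin was -9.77 ± 1.52 for Stfa3, -8.80 ± 1.03 for Krtap19-1, -6.38 ± 1.02 for S100a8, -5.95 ± 0.72 for Saa3 and -5.57 ± 0.65 for Il1b. Retnla went the other way by 5.67 ± 1.02, Krt77 by 4.69 ± 0.76, Casq1 by 4.50 ± 0.71 and Il31ra by 4.06 ± 0.52. Il17c differed by -2.17 ± 0.42 (adjusted p = 0.0258) and Il6 by 0.33 ± 0.58 (adjusted p = 0.936). The Il17c value rests on the IL-6KO label, which Il17c goes against if its row reads the transgene. This contrast also holds the difference between the controls: IL-6KO exceeded WT skin by 6.09 in Stfa3 and 6.10 in Krtap19-1. The WT means of both genes lay below the WT array medians, so these sizes are uncertain. Saa3 and Il1b differed by -5.54 and -5.06 between IL-17C+KO involved and IL-17C+ involved skin themselves. With the labels IL-17C+KO involved and uninvolved exchanged, which is left open below, the Saa3 effect would be 7.08 without IL-6 and 6.64 with it. limma called 290 genes in the contrast, 105 higher and 185 lower, at both ages. Hair genes (20 of 30, 26 adjusted over the list alone, median -4.16, adjusted p = 2.31e-37), stress keratins (10 of 22, 16 adjusted over the list alone, median -2.61, adjusted p = 1.41e-23) and muscle markers (15 of 21, 21 adjusted over the list alone, median 3.08, adjusted p = 1.09e-31) were among 14 lists that passed. These 3 had adjusted p = 0.0834 with an estimated correlation, where 0 of the 14 passed. Without the 10-week WT array most calls turned higher (504, with 321 higher and 183 lower), and without the 14-week one 71 passed (12 higher, 59 lower). The count was 137 (20 higher, 117 lower) and 95 (19 higher, 76 lower) without the 10- or 14-week IL-6KO array, and 311 (165 higher, 146 lower) without the 10-week WT and IL-6KO arrays. It was 76 (5 higher, 71 lower) and 161 (27 higher, 134 lower) without the 10- or 14-week IL-17C+ involved array, 76 (6 higher, 70 lower) and 464 (224 higher, 240 lower) without the 10- or 14-week IL-17C+KO involved array (Il6 at -0.53 without the latter and -0.31 without the 14-week IL-17C+ involved array), and 181 with no replicate block.

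Does the difference between skin sites depend on IL-6? It turned over. The involved minus uninvolved difference was lower without IL-6 by -12.95 ± 0.72 in Saa3 (adjusted p = 2.74e-06), -10.54 ± 0.66 in Retnlg, -10.10 ± 0.65 in Il1b, -9.65 ± 0.78 in Tnc and -9.09 ± 0.93 in Krt6b. It was higher by 6.77 ± 1.02 in Retnla, 6.75 ± 0.76 in Krt77 and 5.42 ± 0.52 in Il31ra. Il17c differed by -2.51 ± 0.42 (adjusted p = 0.0067) and Il6 by -1.65 ± 0.58 (adjusted p = 0.217). The Il17c direction is drawn from the IL-17C+ uninvolved label, which Il17c contradicts if its row reads the transgene. limma called 573 genes, 255 higher and 318 lower, at both ages. Neutrophil markers (10 of 14, 11 adjusted over the list alone, median -3.34, adjusted p = 4.68e-24), proteases (11 of 16 lower and 1 higher, 15 and 1 adjusted over the list alone, median -3.71, adjusted p = 2.22e-22) and antimicrobial genes (10 of 16, 13 adjusted over the list alone, median -3.38, adjusted p = 2.87e-22) stayed called at adjusted p = 0.0316 with an estimated correlation. Muscle markers (20 of 21, also 20 adjusted over the list alone, median 3.20, adjusted p = 3.1e-30) did not, at adjusted p = 0.0694. The count was 255 (76 higher, 179 lower) and 235 (68 higher, 167 lower) without the 10- or 14-week IL-17C+ involved array, 394 (95 higher, 299 lower) and 506 (284 higher, 222 lower) without the 10- or 14-week IL-17C+ uninvolved array. It was 208 (59 higher, 149 lower) without the 10-week IL-17C+KO involved array, 260 (76 higher, 184 lower) and 296 without the 10- or 14-week IL-17C+KO uninvolved array, and 861 (467 higher, 394 lower) without the 10-week WT and IL-6KO arrays.

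How alike are the transgene effects with and without IL-6? Over all 22180 genes the IL-17C+ involved against WT differences had r = -0.252 (rho = -0.11) with those of IL-17C+KO involved against IL-6KO, and r = 0.377 (rho = 0.217) with those of IL-17C+KO uninvolved against IL-6KO. These pairs share no array, and genes are not independent replicates, so no p is given. Saa3, Il1b, Retnlg and Cxcl3 are among 53 genes higher in both IL-17C+ involved skin (244) and IL-17C+KO uninvolved skin (87), where 0.957 would fall together by chance. Between IL-17C+ involved skin (155 lower) and IL-17C+KO involved skin (38 lower) 0 genes are shared, where 0.266 would be. A count of 0 is what chance would most often give here, so it does not show that the effects are unlike. In IL-17C+KO involved against IL-6KO skin 0 genes were called higher, so none could be shared upward. The first r was -0.084 (rho = 0.116) at 10 weeks alone and -0.039 (rho = 0.003) at 14 weeks alone, so its size, and the sign of rho, depend on averaging the ages. It was -0.015 without the 10-week IL-17C+KO involved array and -0.073 without the 14-week WT array. Without the 14-week IL-6KO array r was -0.143.

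Does skin change between 10 and 14 weeks over all groups? No gene passed: limma called 0 of 22180 (1856 at unadjusted p under 0.05, 1109 by chance). The genes with the smallest p were small RNAs, Snora75 and Mir505 (both adjusted p = 0.132). Il1a (2-fold), Retn at 0.91 ± 0.21 and Tyrp1 at 0.73 ± 0.19 did not pass (each adjusted p = 0.571), nor did Il6 (0.06, adjusted p = 0.938) or Il17c (0.13, adjusted p = 0.797). By camera 12 of 24 lists passed, 8 upward and 4 downward, among them hair genes (0 of 30 past either threshold, median 0.43, adjusted p = 5.3e-07) and adipocyte markers (0 of 13, 1 adjusted over the list alone, median 0.37, adjusted p = 6.34e-06). With an estimated correlation these had adjusted p = 0.592 and 0.496, and 0 of the 12 lists passed. Il6 turned to -0.23 without the 10- or 14-week IL-17C+KO involved array and Il17c to -0.01 without the 10- or 14-week IL-17C+ involved array, and the muscle median was -0.02, its test upward, without the 10- or 14-week IL-17C+KO involved array. With the Y-linked mean as a covariate 1 gene passed and Il6 was at -0.01.

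Does the loss of IL-6 act otherwise at 14 than at 10 weeks? In the limma fit with 1 age slope per genotype 0 genes passed (1175 at unadjusted p under 0.05, 1109 by chance, 0.866 the smallest adjusted p), Saa3 being 1 of the 5 genes with the smallest p. Il6 differed by 1.42 ± 0.48 (adjusted p = 0.866) and Il17c by 0.08 (adjusted p = 0.985). This fit averages both skin sites, so changes of opposite sign at the 2 sites cancel in it and cannot be found. The median change from 10 to 14 weeks was 2.15 in involved and -1.53 in uninvolved skin for hair genes. For antimicrobial genes it had the same sign, 0.76 and 0.96. Camera passed 11 of 24 lists, all upward (0 with an estimated correlation), such as antimicrobial genes (0 of 16, 1 adjusted over the list alone, median 0.71, adjusted p = 3.64e-05) and proteases (0 of 16, 5 adjusted over the list alone, median 0.83, adjusted p = 1.5e-05), both with adjusted p = 0.538 with an estimated correlation. Without the 10- or 14-week IL-17C+KO uninvolved array 8 genes passed each time, and the medians of the stress keratin (0.46) and proliferation (0.23) lists turned to -0.29 and -0.22 without the 10- or 14-week IL-17C+KO involved array. Il17c turned to -0.63 without the 10- or 14-week IL-17C+ uninvolved array, to -0.03 without the 10- or 14-week IL-17C+KO involved array, to -0.58 with the Y-linked mean as a covariate and to -0.09 with 1 age slope for the IL-6-deficient groups and 1 for the others.

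Side by side and without a test, the loss of IL-6 in involved skin went with a hair list median of -2.88 at 10 weeks and -0.29 at 14 weeks, 1 array on each side. Tchh of the inner root sheath differed by -6.18 and -0.44, Krt71 by -5.96 and -0.30, Stfa3 by -6.26 and -1.10, Mstn of muscle by 3.19 and -0.61 and Ifitm6 by 0.24 and -2.95. Stress keratins had medians of -1.71 and -0.67, proliferation genes -0.59 and 0.15, neutrophil markers -2.05 and -1.46, antimicrobial genes -1.29 and -1.19, and fibroblast genes -1.09 and -1.11. In uninvolved skin the medians of stress keratins were 2.32 and 2.14, of antimicrobial genes 1.43 and 3.18, of proteases 1.24 and 2.60, and of hair genes 0.27 and -1.36. Muscle markers moved against inflammation at both ages, with 2.32 and 1.20 in involved and -2.08 and -1.06 in uninvolved skin. Except for proliferation at 14 weeks (above 87.3% of random lists), all these medians stood at percentile 0 or 100 of 10000 random lists matched on expression. Genes of a random list do not move together as list members can, so 1 differing pool can give such percentiles. They are therefore no support for an effect of IL-6 loss.

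**Figure D3:**
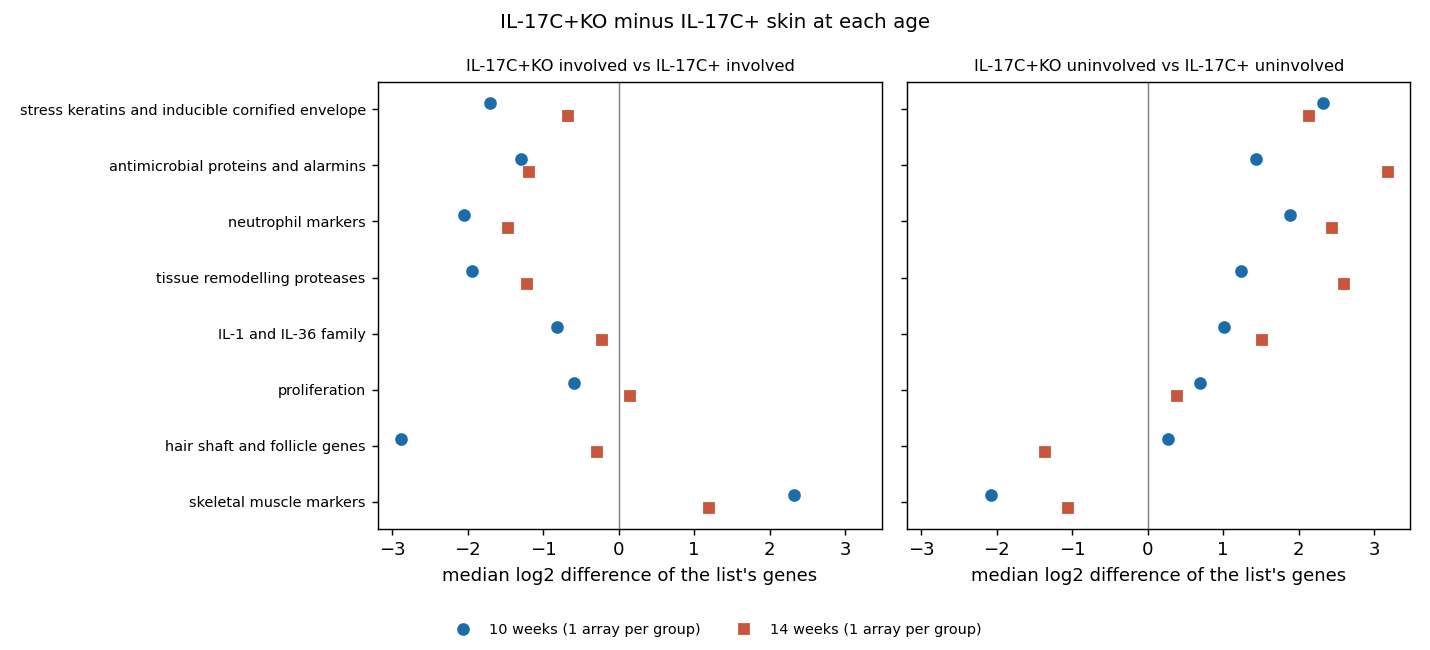
Median log2 difference (horizontal axis) of 8 gene lists (vertical axis) between skin labelled IL-17C+KO and IL-17C+, in involved (left) and uninvolved (right) skin. Blue circles are 10 weeks and red squares 14 weeks, each point 1 list at 1 age. Stress keratins lie at -1.71 and -0.67 in involved but at 2.32 and 2.14 in uninvolved skin.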

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

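Every test of an explanation in this part was chosen only after its pattern was seen. The 2 interactions below were planned before the data were examined.

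Some results differ between groups of samples. The first contrast also holds the difference between skin labelled IL-6KO and WT. In it, by the labels, the effect of the transgene in involved skin depended on IL-6 in 290 genes and 14 gene lists. Of these lists 0 passed with an estimated correlation. Il17c differed by -2.17, Retnla by 5.67, Krt77 by 4.69, Casq1 by 4.50, C7 by 4.28, Fcgbp by 4.08, Il31ra by 4.06, Myh1 by 3.85, Mybpc2 by 3.82, and Pdlim3 and Trdn by 3.61 each. On the lower side stood Stfa3 at -9.77 and the hair genes Krtap19-1 at -8.80, Krtap8-1 at -8.27, Krtap19-9b at -8.25, Krtap19-5 at -8.15, Krtap22-2 at -7.57, Krtap6-5 at -7.25, Krtap16-3 at -7.22, Krtap19-2 at -6.87 and Krtap1-5 at -6.86. By the labels, the difference between involved and uninvolved transgenic skin depended on IL-6 in 573 genes and 16 lists, 3 of which passed with an estimated correlation, and Il17c was at -2.51. Both contrasts rest on the IL-17C+KO site labels, whose exchange is left open below. Higher were Retnla at 6.77, Krt77 at 6.75, Il31ra at 5.42, Fcgbp at 5.06, Xirp2 at 5.04, Lce1m at 5.03, Skint6 at 4.92, Skint9 at 4.72, Casq1 at 4.67 and Myh1 at 4.50. Lower were Saa3 at -12.95, Stfa3 at -11.24, Retnlg at -10.54, Stfa2l1 at -10.23, Il1b at -10.10, Tnc at -9.65, S100a9 at -9.55, S100a8 at -9.35, Cxcl3 at -9.27 and Krt6b at -9.09.

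Array rows that name several genes or none were not part of the gene tests. Of 17824 such rows, 11 passed limma's adjusted p of 0.05 in IL-17C+ involved against WT, 1 in IL-6KO against WT, 1 in IL-17C+KO against IL-17C+ uninvolved skin, 11 in IL-17C+ involved against uninvolved skin, 10 in the transgene by IL-6 and 18 in the site by IL-6 interaction. In the first comparison 9 of the 11 rows name the small nuclear RNA genes Rnu1b1, Rnu1b2 and Rnu1b6 and hold the same value, 3.925 higher, so they count as 1 finding.

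Il17c lay at the WT level in skin labelled IL-17C+ uninvolved and above it in skin labelled IL-6KO. An exchange of these labels might leave a trace around Il6, because a disrupted allele carries its neighbours along: of the 200 genes nearest to it, 4 separated the 6 arrays then labelled IL-6-deficient from the other 6, and 0.815% of other windows (3 of 368) held as many. Neighbouring windows overlap and share genes, so the 368 are not independent and this share is only a rough guide. Of the 4 ways of assigning these labels that were tried, the given one had 0 such genes near Il6 (35 in all), an exchange at both ages 4 (111), at 10 weeks only 3 (332) and at 14 weeks only 0 (11), where 48 in all would be due to chance. By the share of windows alone, the rule written down first, the exchange would count as fitting, but the 4 genes part the arrays by only 0.06 (Rbm33), 0.01 (Dnajc5g), 0.03 (Zfp512) and 0.01 (Uvssa), and a minimum gap of 0.10 was required after these gaps were seen. If instead the Il17c row reads only the endogenous gene and follows inflammation, Il17c and the antimicrobial genes should lie above both WT arrays on the same arrays. They agreed in this on 9 of 10 (Il17c above on 8, antimicrobial genes on 9). With nearly all arrays above WT in both, agreement on most of them follows from these counts alone and decides nothing. The 2 explanations cannot be told apart here.

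Involved minus uninvolved differences had opposite signs with and without IL-6. A mere weakening of the difference is argued against by the slope over the 357 genes called with IL-6, -0.55 on average and -0.73 and -0.38 at the 2 ages, but only if the site labels hold, since an exchange turns the sign of the slope and leaves a weakening open. An exchange of the labels IL-17C+KO involved and uninvolved could give the pattern, but the share of these genes with the opposite sign without IL-6 at both ages, 75.4% (96.1% at 10 and 77.3% at 14 weeks), only restates it. The same holds for inflammation that moved to skin that looks uninvolved, where antimicrobial genes were higher by 1.89. The 2 explanations cannot be told apart, since both need these same values.

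The WT and IL-6KO arrays at 10 weeks stood apart from the other 10. In both, 249 genes lay beyond all other arrays with a mean log2 difference over 1 (203 higher). The next highest of 66 pairs, the 2 arrays of IL-17C+ involved skin, had 207, and the median was 12. Raised background stays open: the 1390 olfactory and vomeronasal receptor genes, silent in skin, lay above the other 10 arrays (-1.65 to -1.53 relative to the array median) in WT (-1.51) but not in IL-6KO (-1.66), the lower minus the highest other being -0.13, yet they are 18.5% of the 249 genes (46) and 6.27% of all genes. By the median alone it would count as excluded, and the share was weighed after both values were seen. A compressed intensity range is possibly part of it: the spans of 5.42 and 5.60 lay below the others, which reached from 5.66 to 5.88 (the higher minus the lowest other: -0.06). A true difference of 10-week skin labelled as free of the transgene was not tested apart from these and stays open.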

How the results depend on the processing

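Of 4614 repeats of named genes 3984 were the same, 591 weaker, 10 stronger and 29 reversed; of 3501 repeats of lists 3046 were the same, 429 weaker and 26 reversed; of 288 list medians at 1 age 277 were the same and 11 moved. The fit on only the 4 arrays of the 2 groups and the one without the 10-week WT and IL-6KO arrays were chosen after seeing the data, all others before. The cause was not tested unless stated. When 1 array of a group is left out, the lone one is assumed to vary like the other groups. With an estimated correlation 156 of 168 list calls were weaker, and with fry 105 of 168. Counts are genes past adjusted p 0.05.

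With no replicate block the counts were 7 in IL-17C+ uninvolved vs WT, 14 in IL-17C+KO involved vs IL-6KO, 26 in IL-6KO vs WT and 181 in the transgene by IL-6 interaction. A replicate block of genotype and age gave 62 in IL-17C+KO involved vs uninvolved (7 higher, 55 lower). Deviations from the group means of arrays of the same age correlated over 15 pairs at -0.212 to 0.523 (median 0.0668, 7 above 0.1).

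With eBayes without the trend the counts were 3 in IL-17C+ uninvolved vs WT, 15 in IL-17C+KO involved vs IL-6KO and 63 in IL-6KO vs WT. Quantile normalization again gave 3 and 22 in the first 2 of these, and only genes above the array median in at least 2 arrays gave 19 in the first and a correlation of transgene effects of -0.309. That correlation was -0.11 with Spearman, -0.084 at 10 weeks alone and -0.039 at 14 weeks alone (Spearman 0.116 and 0.003). The Y-linked mean as a covariate gave 27 in IL-17C+ uninvolved vs WT, 66 in IL-6KO vs WT (43 higher, 23 lower), 1 for age, an Il6 age difference of -0.01, an Il17c age by IL-6 difference of -0.58 and a correlation of -0.297. With 1 age slope for the IL-6-deficient groups and 1 for the others Il17c was at -0.09.

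The skeletal muscle list mean as a covariate gave 0 by limma in IL-17C+ involved vs WT (1002 at unadjusted p under 0.05), IL-17C+KO involved vs IL-6KO (553), IL-17C+KO involved vs IL-17C+ involved (846) and IL-17C+ involved vs uninvolved (720), 29 in IL-17C+KO involved vs uninvolved (2 higher, 27 lower) and a correlation of -0.216. By construction it takes out what goes with muscle and widens the errors. In IL-17C+ involved vs WT it turned Il6 to -0.43, Mybpc2 to 0.68 and the homeostatic differentiation, proliferation and hair medians to -0.13, -0.13 and -0.03. In IL-17C+ involved vs uninvolved it turned Il6 to -0.72, Mybpc2 to 0.65 and proliferation to -0.26, and in IL-17C+KO involved vs IL-17C+ involved stress keratins to 0.05 and proliferation to 0.35.

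WT as the control gave 5 (4 higher, 1 lower) for IL-17C+KO involved skin, with Il17c at 0.65, Krtap19-1 at 1.21, Krtap19-9b at 0.56, Krtap19-5 at 0.46 and Krtap6-5 at 0.92, and the macrophage, melanocyte, muscle and fibroblast medians at -0.32, 0.15, -0.53 and -0.84. For IL-17C+KO uninvolved skin it gave 308 (248 higher, 60 lower), Il17c at 1.39 and the homeostatic differentiation, macrophage and hair medians at 0.44, -0.14 and 1.34. By construction these contain the difference between IL-6KO and WT.

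Only the 4 arrays of the 2 groups gave 883 in IL-17C+ involved vs WT (463 higher, 420 lower). Without the 10-week WT and IL-6KO arrays the counts were 1 in IL-17C+ uninvolved vs WT (0 higher, 1 lower), 2 in IL-17C+KO involved vs IL-6KO (1 and 1), 34 in IL-17C+KO uninvolved vs IL-6KO (31 and 3) with Il17c at 0.11, 13 in IL-6KO vs WT (9 and 4), 225 in IL-17C+KO vs IL-17C+ involved (114 and 111), 666 in IL-17C+ involved vs uninvolved (239 and 427) and 861 in the site by IL-6 interaction (467 and 394), and the correlation was -0.202.

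Leaving out each array in turn gave these lowest and highest limma counts, with genes at unadjusted p under 0.05 beside a 0: IL-17C+ involved vs WT 65 to 509, IL-17C+ uninvolved vs WT 0 (804) to 87, IL-17C+KO involved vs IL-6KO 0 (493 and 1562) to 62, IL-17C+KO uninvolved vs IL-6KO 15 to 164, IL-6KO vs WT 7 to 153, IL-17C+KO vs IL-17C+ involved 23 to 244 and uninvolved 59 to 200, IL-17C+ involved vs uninvolved 63 to 519, IL-17C+KO involved vs uninvolved 16 to 160, transgene by IL-6 71 to 504, site by IL-6 208 to 731, age 0 to 0 (990 to 3191) and age by IL-6 0 (794 to 1850) to 8. The correlation ran from -0.364 to -0.015.

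Genes and list medians that turned in some left-out fit, or whose list test did, ran from lowest to highest as follows. Il17c: -0.80 to 0.06 in IL-17C+ uninvolved vs WT, -0.19 to 0.12 in IL-17C+KO uninvolved vs IL-6KO, -0.01 to 0.27 with age and -0.63 to 0.78 in age by IL-6. Il6: -0.70 to 1.04 in IL-17C+KO vs IL-17C+ involved, -0.08 to 1.21 in IL-17C+ involved vs uninvolved, -0.53 to 1.20 in transgene by IL-6 and -0.23 to 0.28 with age. Muscle: -0.01 to 1.42 in IL-17C+KO involved vs IL-6KO and -0.36 to -0.02 with age. Proliferation: -0.57 to 0.02 in IL-17C+KO vs IL-17C+ involved and -0.22 to 0.64 in age by IL-6, where stress keratins ran from -0.29 to 1.27. Homeostatic differentiation: -0.03 to 0.55 in IL-17C+KO vs IL-17C+ uninvolved and 0.00 to 0.71 in IL-17C+KO involved vs uninvolved. Hair: -1.18 to -0.02 in IL-17C+KO vs IL-17C+ uninvolved. Fibroblast genes: -0.03 to 0.93 in the same comparison and 0.00 to 0.89 in IL-17C+ involved vs uninvolved.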

Other observations

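The age exchanges of this part were planned before the data were examined, and the hypotheses on muscle, hair and Osm were picked only after the results were seen.

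With ages exchanged within the groups in all 32 ways, limma called 0 genes with the true ages and 0 in every other (highest other 0), so 32 of 32 was fixed by the count of 0 and says nothing about chance. At unadjusted p under 0.05 the true ages gave 1856 genes, 6 of 32 exchanges gave at least as many, and the highest other gave 3644 with the 2 IL-17C+ uninvolved pools exchanged, so chance cannot be excluded. What makes that exchange the highest was not tested. For the age by IL-6 interaction the real count was 0 and the highest other 0 (8 of 8), and 8 exchanges cannot reach a share under 0.05.

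Skeletal muscle genes were low where inflammatory genes were high in skin labelled IL-17C+ involved. One hypothesis is that thickened, inflamed skin holds a smaller share of the muscle layer in each biopsy. With the skeletal muscle list mean as a covariate, Casq1 in IL-17C+ involved against WT skin went from -3.48 to -0.92, Stfa3 from 8.24 to 3.38, S100a8 from 6.39 to 2.72, Krt16 from 5.70 to 1.70 and Saa3 from 6.64 to 5.70, none passing any more, and the count went from 399 to 0. Casq1 belongs to that list, so its own shrinkage was built into the covariate and says nothing about the hypothesis. Casq1 also lay at -2.47 (adjusted p = 0.062) in IL-6KO against WT skin, where the antimicrobial list had a median of 1.06 (adjusted p = 1.03e-09, but 0.211 with an estimated correlation) and Saa3 lay at 0.40 (adjusted p = 0.909). A dissection of epidermis, dermis and muscle before RNA is taken would test how much of the muscle signal is sampling.

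Hair shaft genes differed between the groups labelled WT and IL-6KO: Krtap19-1 averaged 3.14 and 9.24 in them. In IL-17C+KO involved skin its sign depends on the control, -4.89 against IL-6KO and 1.21 with WT as the control. A hypothesis is that the pools differ in hair cycle stage, and staging the follicles on sections of the same skin would test it. Osm, a relative of IL-6, rose by 1.85 in IL-17C+KO uninvolved skin and fell by 1.73 in IL-17C+KO involved skin, each against IL-17C+ skin of the same site label, and Timp1 differed by 3.24 and -2.79. Whether Osm keeps Timp1 high without IL-6 can be tested by blocking its receptor in these mice, once the labels are settled.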
